A study of Mus musculus with 6 samples.

How the data were processed

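Total RNA of sorted marrow cells was extracted with the RNeasy Micro kit and 100 ng was labelled with biotin by an Affymetrix 3' IVT kit, per the labels. The authors deposited 1 table of log2 expression values with 45101 probe sets and 6 arrays. GCRMA is the processing tool that the submitters' processing notes name; its version and settings, the scanner software and any filter are not given in the sources used here. That the deposited values are log2 was read from their range, about 1 to 15 with none negative, and from their near-equal distributions on the arrays. They are normalized between arrays as far as the tool's name tells, and were used as deposited.

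Samples were grouped by their titles and sorted-cell labels into GFP_hi and GFP_lo, with 3 arrays each and replicate letters a, b and c from the titles. Probe sets were named from GEO's platform annotation: 34958 had 1 gene symbol, 932 had several and, controls aside, 9160 had none given. Gene IDs of 34754 probe sets were found in a RefSeq table of the mouse assembly GRCm38.p6, which was used to update symbols. No coordinates were used. Probe sets with several symbols were tested but named no gene.

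Leaving out 64 control probe sets, a probe set was tested if it exceeded the median of its own array on at least 3 of the 6 arrays, which 22956 did. Of these, 19113 had 1 symbol and stood for 10810 genes, each represented by its probe set with the highest mean over all arrays. In 59 genes some probe sets were called in opposite directions. GFP_hi minus GFP_lo was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Differences are in log2, and where a group lay below the median of each of its arrays, the fold is given as at least the ratio to those medians.

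Before the data were examined, 29 gene lists were fixed. They cover sort markers, histamine genes, granule and neutrophil genes, other cell types the gate could hold, cell cycle, regulators, metabolism and ribosomes. Lists with at least 5 tested members were tested with camera (preset correlation 0.01, adjusted over the lists), with camera on an estimated correlation, and with fry, a rotation test of whether a list moves on balance one way. The genes to be named were also set by a rule beforehand. They are the 6 sort markers, the 10 largest rises and 10 largest falls among changed genes without overlap between groups, and up to 4 members of each list with the smallest adjusted p. Where no member of a list passed, up to 2 with the largest difference were named. Clone names and immunoglobulin or T cell receptor segments were left out of the largest changes. In some genes named by this rule, not all tested probe sets shared the gene's call, though no call was opposite. In Cd80 1 of 3 shared it, and in Vcam1 and Cdca8 2 of 3. In Steap4, Tpx2, Uhrf1, Atp5o and Pes1 it was 1 of 2, in Slc2a3 2 of 4, in Itga4 3 of 5 and in Ccnd2 6 of 7. RNA quality was tested with exact permutation tests, whose smallest p for 3 against 3 is 0.1.

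Alternatives changed the filter, the variance model, array weights, the normalization (quantile, or centring on tested probe sets or on ribosomal protein genes), the probe sets of a gene, a size threshold of 1 log2, the replicate letter as a block, each sample left out in turn, the correlation, the set test and the inclusion of dim list members. Centring on the poly-A control RNAs was added after these were seen to differ between the groups. The fit was tested on simulated data for this comparison with 10810 genes, of which 200 were changed. It recovered 32% of those changed by 0.5 log2 and 74% of those changed by 1 log2, with 0 unchanged genes called. It called the raised list and 0 of 20 unchanged lists. The simulated noise was drawn independently for each probe set, so list calls under correlation between genes were not checked. Far fewer genes were changed than the 5263 called in the data, so these rates may not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.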

Results

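Gene expression was measured on Affymetrix arrays in myeloid cells from the femur and tibia marrow of female HdcGFP mice on a C57BL/6 background. These mice carry a green fluorescent reporter for Hdc, the gene of histidine decarboxylase, the enzyme that makes histamine. Cells bearing CD11b and Gr1 were sorted by reporter signal into a positive or high group (GFP_hi, 3 samples) and a negative or low group (GFP_lo, 3 samples). The sorted-cell label is Gr1-positive for all 6 samples, but the description of GFP_lo replicate b reads Gr1-negative. The labels do not say whether the samples came from separate mice, so p-values measure only the spread between these samples, which may be technical. The deposited log2 values had medians between 2.82 and 2.88 on the 6 arrays. Arrays of one group correlated at 0.995 to 0.997, and arrays of different groups at 0.961 to 0.967. The number of arrays limits the precision of every value.

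The comparison asks how CD11b+Gr1+ marrow cells with high Hdc reporter signal differ from those with little or none. GFP_hi cells had lower transcripts of monocytes (list median −2.34; adjusted p = 0.0648 with an estimated correlation) and of MHC class II antigen presentation (−2.12; 0.154). They had higher transcripts of primary granules (median 1.33; 0.0799), among them proteases and myeloperoxidase, and of mature neutrophils (0.56; 0.0398). The basophil protease Mcpt8 was 18.5-fold higher in GFP_hi (3.41 ± 0.10 against 7.62 ± 0.31 on the log2 scale, mean ± SD, n = 3 each) and the fractalkine receptor Cx3cr1, a monocyte gene, was 80.1-fold lower (10.39 ± 0.05 against 4.07 ± 0.30). Ribosomal protein (median −0.58; adjusted p = 0.0648 with an estimated correlation), nucleolar (−0.63; 0.0799) and mitochondrial respiratory chain transcripts (−0.44; 0.137) were lower in GFP_hi on the deposited scale. The direction of the nucleolar and respiratory chain medians turned with ribosomal centring, which for ribosomal protein genes themselves is no test.

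Of 10810 genes tested with limma, 2275 were higher and 2988 lower in GFP_hi at an adjusted p under 0.05. Without GFP_lo replicate b, 2081 were higher and 2734 lower. The falls were larger than the rises: 946 genes fell and 164 rose by at least 1 log2, and 173 fell and 2 rose by at least 3. In 6407 genes (59.3%) all 3 arrays of one group lay above all 3 of the other, where chance gives 10%. The median difference over all genes was 0.0023 on the deposited scale, and the differences given here are on that scale. Centring the arrays on their ribosomal protein genes adds 0.74 to every difference, on the median of tested probe sets 0.20, and on the bacterial poly-A control RNAs −0.45. A fall smaller than 0.74 thus turns positive with ribosomal centring, and a rise smaller than 0.45 turns negative with poly-A centring. Higher genes made up 43.2% of the changed genes on the deposited scale, 50.2% after quantile normalization, 68.1% after median centring, 90.5% after ribosomal centring and 5.10% after poly-A centring. Of the genes named by rule, 15 kept their direction and lost their call with poly-A centring: Car2, Ccr1, Dusp1, Hk3, Ifitm1, Il1b, Mcm2, Pfkfb4, Prom1, Rsad2, Selp, Slc2a1, Slc2a3, Stat3 and Tpx2. With ribosomal centring 6 did: Atp5o, Casp8, Klrd1, Ndufa9, Rnase2a and Uqcrfs1. With median centring Ccnb2 and Hrh1 did. The position of a list relative to the median of all genes was the same under all 3 centrings.

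Gene groups were 29 lists fixed before the data were examined, of which 27 had at least 5 tested members. By limma's camera with a preset correlation of 0.01, 12 lists stood above the other genes and 6 below. With a correlation estimated per list, 1 of the 18 calls was kept, that of tertiary granule and mature neutrophil genes. The estimate lay under the preset for basophil and mast cell (−0.061), dendritic cell (−0.042), stem and progenitor (−0.024) and nucleolar genes (0.0082). These lost their calls too, so a higher correlation was not the reason there. In the other lists that lost their call the estimate lay above the preset. The estimate for mature neutrophil genes was 0.0097, under the preset, yet their camera adjusted p went from 2.77e-13 to 0.0398. The adjusted p-values of this form thus do not measure correlation between genes alone. What else sets this form of camera apart was not tested. By fry, a rotation test of whether a list moves on balance one way, 23 of the 27 lists passed, and 17 of the 18 calls were kept. Unlike camera, fry does not compare a list with the other genes, and 48.7% of all tested genes changed. Passing by fry thus says little about whether a list stands apart from the other genes. Counts of members are adjusted over all probe sets tested, and the count adjusted over the list alone was the same unless another is given. Members named as the few that went a given way, where they fall outside the naming rule, were chosen after their values were seen.

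**Figure D1:**
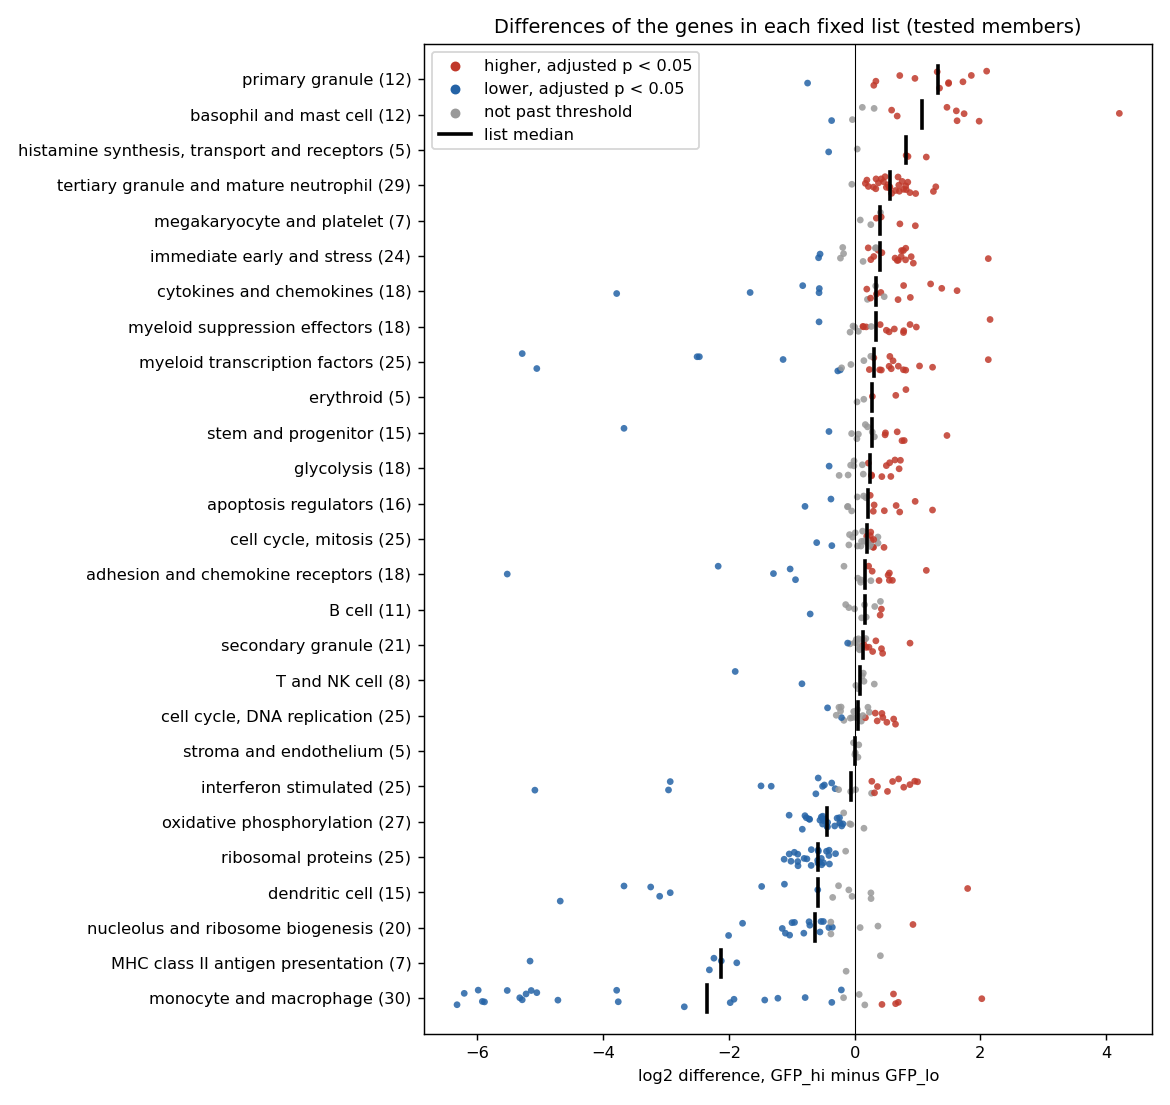
Log2 difference (GFP_hi minus GFP_lo, x axis) of every tested gene of the 27 lists with at least 5 tested members, with the number tested in brackets. Points are genes, coloured by their limma call at an adjusted p under 0.05, and black bars are list medians, from 1.33 for primary granule genes to −2.34 for monocyte and macrophage genes; medians above 0 and under 0.45 turn negative with poly-A centring, and those that fell by less than 0.74 turn positive with ribosomal centring, for ribosomal protein genes by construction. Hdc, the basis of the sort, is a member of the histamine list.

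Hdc itself, the basis of the sort and so no finding between the groups, was 11.19 ± 0.03 in GFP_lo and 12.01 ± 0.06 in GFP_hi (log2, mean ± SD, n = 3), a rise of 0.82 (SE 0.05, limma adjusted p = 1.28e-06). In GFP_lo it already lay far above the array medians. Its other probe set rose by 0.59. Besides Hdc, 4 genes of histamine synthesis, transport, breakdown and receptors were tested, too few for a list test, and 2 were higher and 1 lower. With Hdc the list has a median of 0.82, which is the difference of Hdc itself, and a camera adjusted p of 0.0590. It passed upward without GFP_hi replicate a (0.0448), without GFP_lo replicate a (0.0417), without the filter on dim probe sets (median 0.27, 0.0101) and by fry (0.000873). Since Hdc is a member, the sort fixed part of each of these values. Hnmt, which degrades histamine by methylation, rose by 1.14, and Hrh2, the H2 receptor, by 0.85. Hrh1, the H1 receptor, was at least 1.08-fold lower, since it fell below the array medians in GFP_hi. Its measured fall of 0.41 lost its call without GFP_hi replicate a (−0.39, adjusted p = 0.0504) and with median centring (−0.21, 0.130), and turned to 0.33 and passed with ribosomal centring (0.0247). The vesicular amine transporter Slc18a2 was 3.41 and 3.45.

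Of the other sort markers, Itgam, which encodes CD11b, differed by 0.26 (11.58 ± 0.23 against 11.84 ± 0.13, limma adjusted p = 0.0745), and by 0.39 without GFP_lo replicate a (adjusted p = 0.00400). It passed with median centring (0.46, adjusted p = 0.00555) and ribosomal centring (1.00, 3.42e-05). With poly-A centring the median of the 3 tested markers turned to −0.19. Ptprc, which encodes CD45, was higher by 0.15 (adjusted p = 0.0376). That call was lost without any 1 of 5 samples, GFP_hi c being the exception, with values of 0.14 (without GFP_hi a), 0.11 (GFP_hi b), 0.16 (GFP_lo a), 0.12 (GFP_lo b) and 0.17 (GFP_lo c). The call was also lost with the replicate block (limma adjusted p = 0.105) and without the variance trend (0.208). Poly-A centring turned the difference to −0.30. Adjusted over the list alone, all 3 tested markers, Hdc among them, were higher. Of the genes of the Gr1 antigens, Ly6g had no probe set of its own. The 1 probe set that the annotation gives to both Ly6c1 and Ly6c2 was 13.38 and 13.29 (adjusted p = 0.0980) and cannot tell these genes apart.

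Primary granule genes, which neutrophil precursors express first, were higher in GFP_hi for 11 of 12 tested, with a median of 1.33 (camera adjusted p = 5.74e-07; adjusted p = 0.0799 with an estimated correlation). Mpo, myeloperoxidase, rose from 11.34 ± 0.03 to 12.83 ± 0.07 (1.49, SE 0.05, limma adjusted p = 1.42e-08). Elane, neutrophil elastase, rose by 1.72, Ctsg, cathepsin G, by 1.31, and Nkg7 and Cst7, a cystatin that inhibits granule cathepsins, by 2.10 and 1.86. The lysosomal enzyme Gusb was the member that fell, by 0.75.

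Secondary granule genes shifted little: 10 of 21 were higher and 1 lower, with a median of 0.13 that turned to −0.32 with poly-A centring (camera adjusted p = 0.00120; adjusted p = 0.184 with an estimated correlation and 0.335 with poly-A centring). Arg2, a mitochondrial arginase, rose by 0.88, Cd177 by 0.45, Padi4, which citrullinates histones, by 0.43 and Ceacam10 by 0.29. Lyz2, lysozyme, fell by 0.11 from 14.57. The granule proteins Ltf (14.06 and 14.13) and Camp (14.51 and 14.57), named after their values were seen, lay close to the brightest values of the arrays in both groups.

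Genes of tertiary granules and mature neutrophils were higher in GFP_hi for 28 of 29 tested, with a median of 0.56 (camera adjusted p = 2.77e-13; adjusted p = 0.0398 with an estimated correlation). Csf3r, the G-CSF receptor, rose from 11.70 ± 0.05 to 12.41 ± 0.05 (0.71, SE 0.05, limma adjusted p = 2.22e-06). The metalloreductase Steap4 rose by 1.25, the cytokine gene Il1b by 0.69 and the inhibitory receptor gene Cd300lf by 0.70. Lmnb1 was the member that did not pass (10.04 and 9.99). Monocyte markers moved the other way between the same samples. The 3' to 5' signal gap, a sign of RNA quality, was 0.32 larger in GFP_hi for Gapdh and 0.061 larger for beta-actin.

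Monocyte and macrophage genes were lower for 22 of 30 tested and higher for 5, with a median of −2.34 (camera adjusted p = 2.12e-09; adjusted p = 0.0648 with an estimated correlation). Their mean per array was 9.98, 10.02 and 10.01 in GFP_lo replicates a, b and c, of which b has the differing description, and 7.34, 7.36 and 7.28 in GFP_hi. Ms4a6b fell from 12.14 ± 0.07 to 5.94 ± 0.06 (−6.21, SE 0.08, limma adjusted p = 7.19e-11). The fibronectin gene Fn1 fell by 5.23, S100a4 by 5.33, the coagulation factor gene F13a1 by 3.76 and Ccr2, the receptor that draws monocytes out of marrow, by 5.52. The 5 higher members were Vcam1 (2.02), C1qb (0.70), Fcgr4 (0.65), C1qa (0.62) and Treml4 (0.44), of which Vcam1 and the complement genes are known from tissue macrophages.

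MHC class II antigen presentation genes were lower for 5 of 7 tested, with a median of −2.12 (camera adjusted p = 0.00191; adjusted p = 0.154 with an estimated correlation), and 1 was higher adjusted over the list alone. H2-DMa fell by 5.16, the class II chain genes H2-Aa and H2-Ab1 by 2.31 and 2.12, and the invariant chain gene Cd74 by 1.87. Dendritic cell genes were lower for 8 of 15 (9 adjusted over the list alone) and higher for 1, with a median of −0.59 that turned to 0.16 with ribosomal centring (camera adjusted p = 0.00731; adjusted p = 0.120 with an estimated correlation). That call was lost with the level filter applied to all 6 arrays (median −0.22, adjusted p = 0.245). Flt3, the receptor of a dendritic cell growth factor, fell by 3.67 to near the array medians and the transcription factor gene Tcf4 by 3.10. Cd209a was at least 19.0-fold and Irf4 at least 6.20-fold lower, each below the array medians in GFP_hi. Itgax, which encodes CD11c, rose by 1.80. The largest falls outside these lists were Ptpro (−7.03), Nxpe4 (−6.68), the prostaglandin-degrading enzyme gene Hpgd (−6.58), Capn2 (−6.13), Ahnak (−6.05) and the lipoprotein lipase gene Lpl (−6.00). The matrix proteoglycan gene Vcan was at least 67.3-fold and Rnd3 at least 58.7-fold lower, against the array medians as the floor.

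**Figure D2:**
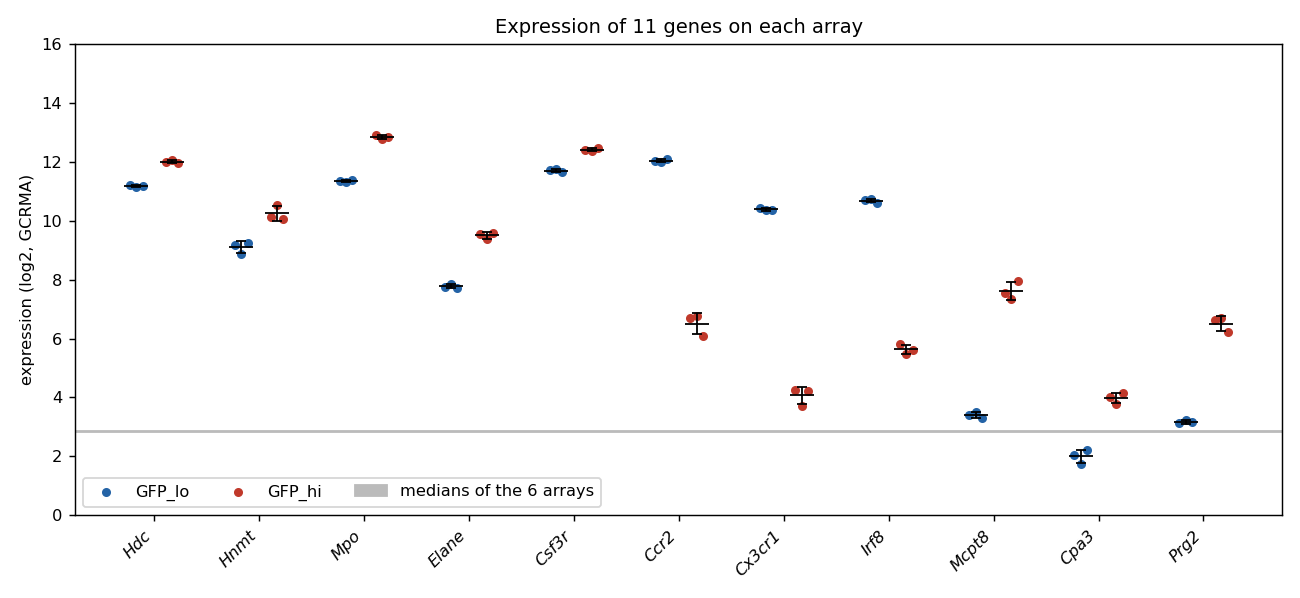
Log2 expression (y axis) of 11 genes on each of the 6 arrays, with GFP_lo in blue and GFP_hi in red; bars show the mean and SD of 3 arrays and the grey band the medians of the arrays. Ccr2, Cx3cr1 and Irf8 lie above 10 in GFP_lo and below 7 in GFP_hi, while Mcpt8 and Prg2 rise from near the array medians.

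Basophil and mast cell genes were higher for 8 of 12 tested (9 adjusted over the list alone) and lower for 1, with a median of 1.07 (camera adjusted p = 9.85e-05, and 0.0738 with an estimated correlation). Some members are shared with other lists: Ifitm1 with mature neutrophils, Kit and Gata2 with stem and progenitor genes and Csf1 with cytokines. Mcpt8 rose by 4.21 (SE 0.17, limma adjusted p = 7.22e-08), and Ms4a2, the beta chain of the IgE receptor, by 1.74 from near the array medians. Cpa3, mast cell carboxypeptidase, was at least 2.23-fold higher, since it lay below the array medians in GFP_lo. Il3ra, the interleukin-3 receptor chain, fell by 0.37. Of 3 tested eosinophil genes, too few for a list test, Prg2, the major basic protein, rose by 3.34 (3.17 ± 0.06 to 6.51 ± 0.26, adjusted p = 1.81e-07) and Siglecf by 1.26. Rnase2a was at least 1.47-fold lower, below the array medians in GFP_hi. The eosinophil genes Epx, Prg3, Ccr3, Il5ra, Alox15 and Gata1 were too dim for the level filter and were not tested. With these dim members the list median was 0.21, against 1.26 without.

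Stem and progenitor genes were higher for 6 of 15 (7 adjusted over the list alone) and lower for 2, with a median of 0.28 that turned to −0.17 with poly-A centring (camera adjusted p = 0.0399; adjusted p = 0.154 with an estimated correlation). Kit, the stem cell factor receptor, rose by 1.47, Myb by 0.79 and Prom1 by 0.48, while Flt3 and Lmo2 (−0.41) fell. The list lost its call without GFP_hi replicate a (median 0.32, adjusted p = 0.0714), GFP_hi replicate c (0.23, 0.0507) or GFP_lo replicate b (0.21, 0.0638). It also lost it without the filter on dim probe sets (median 0.15, adjusted p = 0.170) and with array weights (0.0607), quantile normalization (0.0510), the mean of probe sets (0.101) and centring on the median (0.0858), on ribosomal genes (0.295) or on poly-A controls (0.244). Megakaryocyte and platelet genes were higher for 4 of 7 (6 adjusted over the list alone), with a median of 0.41 that turned to −0.035 with poly-A centring (camera adjusted p = 0.0168; adjusted p = 0.154 with an estimated correlation). With dim members included the median was 0.16, and the call was lost with ribosomal (adjusted p = 0.153) and poly-A centring (0.105). Clec1b, the podoplanin receptor, rose by 0.97 and Selp, P-selectin, by 0.72. Itga2b was at least 1.16-fold higher, since it lay below the array medians in GFP_lo. The calls of Itga2b (measured difference 0.35) and Gp1bb (0.42) did not hold in every sample set. Itga2b lost its call without GFP_hi a (0.30) or GFP_lo a (0.31). Gp1bb lost it without GFP_hi a (0.38), GFP_hi c (0.43), GFP_lo a (0.32) or GFP_lo c (0.45), and with the replicate block (limma adjusted p = 0.0678).

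Erythroid genes were higher for 3 of 5 tested, with a median of 0.28 that turned to −0.16 with poly-A centring (camera adjusted p = 0.0504). The list passed without GFP_hi replicate a (median 0.25, adjusted p = 0.0444) and with the replicate block (0.0441). It also passed without the filter on dim probe sets (0.0338), without the variance trend (0.0383) and by fry (0.000220). The transferrin receptor gene Tfrc rose by 0.82 and the carbonic anhydrase gene Car2 by 0.65. Car1 was at least 1.15-fold higher, below the array medians in GFP_lo. Its measured difference of 0.28 lost its call without GFP_hi a (0.25), GFP_hi b (0.29), GFP_lo a (0.28), GFP_lo b (0.29) or GFP_lo c (0.28). So it did with the replicate block (limma adjusted p = 0.0623) and without the filter on dim probe sets (0.0615). B cell genes were higher for 2 of 11 and lower for 1 (camera adjusted p = 0.291), and by fry they moved up on balance (adjusted p = 0.000304). Cd79b, a chain of the B cell receptor, fell by 0.71. Cd72, whose mean in GFP_lo (2.81) was no higher than the array medians, rose to 3.24. Its measured difference of 0.43 lost its call without GFP_hi c (0.33), GFP_lo b (0.40) or GFP_lo c (0.36), and Dntt (0.41) without GFP_hi a (0.41), GFP_hi b (0.36), GFP_lo a (0.30) or GFP_lo c (0.40). T and NK cell genes were lower for 2 of 8, the granzyme gene Gzma (−1.90) and Klrd1 (−0.84), with a median of 0.09, a mean of −0.24 and a camera adjusted p of 0.943. Of 5 stromal and endothelial genes, 0 passed limma's threshold and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.747), with Col1a1 at 2.89 and 2.94 and Kitl at 2.83 and 2.90, near the array medians.

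Myeloid transcription factor genes went both ways: 14 of 25 were higher and 7 lower (8 adjusted over the list alone), with a median of 0.31 and a mean of −0.26 (camera adjusted p = 0.0510). Irf8, a regulator of monocyte and dendritic cell fate, fell from 10.69 ± 0.07 to 5.63 ± 0.16 (−5.05, SE 0.11, limma adjusted p = 8.53e-10). Klf4, needed for monocyte differentiation, fell by 5.29, Irf5 by 2.51 and Zeb2 by 2.47. Gfi1, a repressor that favours granulocytes and was named after its value was seen, rose by 1.24. The list passed the threshold without GFP_hi a (median 0.31, adjusted p = 0.0444), GFP_hi c (0.36, 0.0459), GFP_lo a (0.35, 0.0198), GFP_lo b (0.28, 0.0357) or GFP_lo c (0.36, 0.0331), and with the mean of probe sets (adjusted p = 0.0348). It did not pass with quantile normalization (camera adjusted p = 0.128), median centring (0.171) or ribosomal centring (0.841). Poly-A centring turned its median to −0.14, with 4 members higher and 10 lower (0.427). By fry its direction was down without passing (adjusted p = 0.250).

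Immediate early and stress genes were higher for 16 of 24 and lower for 2 (17 and 3 adjusted over the list alone), with a median of 0.40 that turned to −0.042 with poly-A centring (camera adjusted p = 9.85e-05; adjusted p = 0.0738 with an estimated correlation). Junb rose by 2.13 (6.05 ± 0.30 to 8.18 ± 0.09), the mRNA decay factor gene Zfp36 by 0.93, Jund by 0.81 and the phosphatase gene Dusp1 by 0.68. Atf3 (−0.55) and Hspa8 (−0.57) fell. Apoptosis regulators were higher for 8 of 16 and lower for 2, with a median of 0.21 that turned to −0.23 with poly-A centring (camera adjusted p = 0.0317; adjusted p = 0.246 with an estimated correlation, 0.118 with poly-A and 0.0721 with ribosomal centring). Their higher members included Pmaip1 (1.24), which promotes death, and Pim1 (0.96) and Mcl1 (0.30), which favour survival, while Casp8 (−0.79) and Bad (−0.38) fell.

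Myeloid suppression effectors were higher for 12 of 18 and lower for 1, with a median of 0.34 that turned to −0.11 with poly-A centring (camera adjusted p = 0.00109; adjusted p = 0.120 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose from 3.96 ± 0.17 to 6.12 ± 0.18 (2.15, limma adjusted p = 3.55e-06). Cd80 rose by 0.98 (1 of its 3 tested probe sets was called higher) and Stat3 by 0.55, and Tgfb1 fell by 0.57. Cytokine and chemokine genes were higher for 10 of 18 (12 adjusted over the list alone) and lower for 5, with a median of 0.34 that turned to −0.10 with poly-A centring (camera adjusted p = 0.0443; adjusted p = 0.210 with an estimated correlation). Without GFP_hi replicate b that call was lost (median 0.31, adjusted p = 0.0515). It was also lost with the filter on all 6 arrays (0.0799), without the variance trend (0.0697), with the mean of probe sets (0.0863), with quantile normalization (0.0555) and with centring on the median (0.171), on ribosomal genes (0.805) or on poly-A controls (0.328). By fry the list leaned down without passing (adjusted p = 0.0668). The macrophage growth factor gene Csf1 rose by 1.63. The 5 that fell were Ccl9 (−3.78), Ccl5 (−1.66), Il18 (−0.83), Tgfb1 and Cxcl10 (−0.56).

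Adhesion and chemokine receptor genes were higher for 8 of 18 (10 adjusted over the list alone) and lower for 5, with a median of 0.16, a mean of −0.35 and a camera adjusted p of 0.185. By fry they moved down on balance on the deposited scale (adjusted p = 0.00406). Poly-A centring gave 1 higher and 9 lower (median −0.28), and ribosomal centring 13 higher and 4 lower (median 0.91). Ccr1 rose by 0.60, while Ccr2, Icam1 (−2.17), Itgb1 (−1.29), Icam2 (−1.03) and the integrin alpha 4 gene Itga4 (−0.94) fell. Interferon-stimulated genes split, with 10 of 25 higher (11 adjusted over the list alone) and 11 lower, a median of −0.063, a mean of −0.41 and a camera adjusted p of 0.747. By fry they moved down on balance on the deposited scale (adjusted p = 0.000669). With ribosomal centring 17 were higher and 5 lower (median 0.68), and with poly-A centring 3 and 14 (median −0.51). Mx1 fell by 5.08, Gbp3 by 2.96 and Xaf1 by 1.49, while the antiviral gene Rsad2 rose by 0.70.

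DNA replication genes were higher for 8 of 25 and lower for 2, with a median of 0.05 (camera adjusted p = 0.185, and 0.00866 by fry, upward). With poly-A centring the median turned to −0.39, with 0 higher and 15 lower (camera adjusted p = 0.270). With ribosomal centring 25 of 25 were higher (camera adjusted p = 0.0403). On the deposited scale Mcm2 (0.51), Rrm2 (0.43) and Uhrf1 (0.36) were higher and Cdt1 (−0.43) and Pcna (−0.21) lower. Mitosis genes were higher for 8 of 25 and lower for 2, with a median of 0.19 that turned to −0.25 with poly-A centring (camera adjusted p = 0.0257; adjusted p = 0.311 with an estimated correlation and 0.232 with poly-A centring). Tpx2 rose by 0.47, Cdca8 by 0.26 and Ube2c by 0.25, and Ccnb2 (−0.36) and Bub1b (−0.60) fell. Outside the lists, the cyclin gene Ccnd2 rose by 1.85.

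Ribosomal protein genes were lower in GFP_hi for 24 of 25 tested, with a median of −0.58 (camera adjusted p = 1.18e-12; adjusted p = 0.0648 with an estimated correlation). Centring on these same genes brings the list near 0 by construction (median 0.16), so it says nothing of their direction. Rpl10a fell by 1.04, Rps19 by 1.01, Rpl22 by 0.96 and Rps18 by 0.90. Between the same samples monocyte genes fell (median −2.34). The 3' to 5' gap of Gapdh was 0.32 larger in GFP_hi, and that of beta-actin 0.061 larger. Nucleolus and ribosome biogenesis genes were lower for 15 of 20 (16 adjusted over the list alone) and higher for 1, with a median of −0.63 that turned to 0.11 with ribosomal centring (camera adjusted p = 0.000882; adjusted p = 0.0799 with an estimated correlation). Fbl, fibrillarin, fell by 2.00, Pes1 by 1.78 and Npm1 by 1.15, while Polr1a, the large subunit of RNA polymerase I, rose by 0.93.

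Oxidative phosphorylation genes were lower for 22 of 27 (24 adjusted over the list alone), with a median of −0.44 that turned to 0.30 with ribosomal centring (camera adjusted p = 1.15e-06; adjusted p = 0.137 with an estimated correlation and 0.660 with ribosomal centring). Ndufs3 fell by 1.04, Uqcrfs1 by 0.83, Atp5o by 0.79 and Ndufa9 by 0.77. Glycolysis genes were higher for 10 of 18 and lower for 1, with a median of 0.24 that turned to −0.20 with poly-A centring (camera adjusted p = 0.00699; adjusted p = 0.154 with an estimated correlation and 0.118 with poly-A centring). The hexokinase gene Hk3 rose by 0.71, the glucose transporter genes Slc2a1 and Slc2a3 by 0.64 and 0.50 and the kinase gene Pfkfb4 by 0.56, and Pfkp fell by 0.41. Monocyte genes, with their median of −2.34, moved in the direction of oxidative phosphorylation genes and against glycolysis genes between the same samples.

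RNA quality was compared through the 3' minus 5' log2 gap of control probe sets, which widens as RNA is shortened. The gap of Gapdh was 0.31 ± 0.05 in GFP_lo and 0.64 ± 0.04 in GFP_hi (n = 3 each, 2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). That of beta-actin was 0.81 ± 0.02 and 0.87 ± 0.04 (exact permutation p = 0.2).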

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

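The tests of the control RNAs and the count of splits were chosen after the result they address was seen. The poly-A control RNAs, bacterial transcripts outside the comparisons, averaged 5.73 ± 0.14 in GFP_lo and 6.17 ± 0.06 in GFP_hi (22 probe sets, n = 3 each). They stood out as a signal outside the measurements compared, and were 0.446 higher in GFP_hi (2-sided exact permutation p = 0.1, the smallest possible). The labels do not say whether or when they were added.

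Brighter hybridization or scanning of the GFP_hi arrays would raise the hybridization controls as much, but these were 0.112 higher (exact permutation p = 0.6). The gap between the kinds of control was 0.334 larger in GFP_hi, just over 2 of its SDs of 0.164. The margin between the nearest arrays was narrow (−2.11 and −2.10). This argues against brightness left in the deposited values as the explanation. Those values were normalized between arrays as far as the tool's name tells, so brightness before normalization cannot be judged from the gap. Less poly-A RNA of the cells per control RNA in the GFP_hi labelling was not tested and stays open, be it from less mRNA per total RNA, less input or a labelling batch, since the labels give neither spike amounts nor batches. All 22 probe sets were higher, by 0.19 to 0.69. With poly-A centring 6460 genes were lower and 347 higher, so the direction of small differences rests on this point.

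By limma, the real grouping of the 6 arrays gave 5263 changed genes and the highest of the other splits 0; at an unadjusted p under 0.05 the counts were 6044 and 289. It was 1 of 10 splits, too few for a share under 0.05.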

How the results depend on the processing

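The one alternative chosen after seeing the data was centring on poly-A control RNAs; the others were fixed before. On the deposited scale 5263 genes changed (2275 higher, 2988 lower) and 18 lists passed. Each count of genes stayed within 1.5 times of these when any sample was left out, and under the other filters, variance models and quantile normalization. Among 117 named genes, 1895 of 1973 alternatives kept direction and side of the threshold, and among 27 lists 468 of 536. The labels do not say whether the replicate letters pair the samples. Deviations of same-letter arrays from their group means correlated at −0.18, −0.30 and −0.22. No positive shared part was thus seen, which does not exclude a pairing. With the replicate block 4340 genes changed (1737 higher, 2603 lower), 4314 of them called the same way without it.

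A size threshold of 1 log2 left 1110 genes (164 higher, 946 lower), by its construction. Centring on the median of tested probe sets gave 4472 higher. Ribosomal centring gave 9296 changed, 8414 higher and 882 lower. Poly-A centring gave 347 higher and 6460 lower, and 11 lists. Each centring adds a constant to every difference and changes the spread within groups; which constant is right, and why list calls were lost, was not tested. With an estimated correlation 1 list passed. By fry, adhesion genes (median 0.16) passed down (adjusted p = 0.00406), and cytokine genes (median 0.34) leaned down without passing (0.0668); the cause was not tested. With dim members included, medians moved to 0.27 (histamine), 0.16 (megakaryocyte) and 0.053 (stroma). Other medians moved too, among them basophil and mast cell (1.07 to 0.59), myeloid suppression (0.34 to 0.17) and cytokine genes (0.34 to 0.20). Those of dendritic cell (−0.59 to −0.35) and interferon-stimulated genes (−0.063 to −0.16) did as well. The camera adjusted p-values of the cytokine list ran from 0.0321 to 0.805 over its alternatives.

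With poly-A centring these genes turned negative: Ube2c −0.20, Cdca8 −0.19, Car1 −0.16, Ceacam10 −0.16, Mcl1 −0.15, Itga2b −0.10, Uhrf1 −0.087, Dntt −0.040, Gp1bb −0.023, Cd72 −0.020, Padi4 −0.019, Rrm2 −0.011 and Cd177 −0.00021. Ptprc (−0.30), Col1a1 (−0.39) and Kitl (−0.38) turned negative and passed. Col1a1 and Kitl lay near the array medians in both groups, so the constant added to them is no sign of lower expression. With ribosomal centring Ccnb2 (0.38), Hrh1 (0.33) and Cdt1 (0.31) turned positive and passed, and Cd79b (0.036) and Nhp2 (0.018) turned positive. Signal over background limits genes near the array medians, where the floor compresses differences.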

Other observations

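All tests in this part were chosen after the results were seen. Of the Ms4a family of tetraspan membrane proteins, 7 of 11 tested genes were lower in GFP_hi and 2 higher. The family was picked because its members were among the largest falls, so a test of it would restate that choice and its p is left out. Ms4a4c (−5.89), Ms4a6c (−5.92), Ms4a6d (−5.72), Ms4a8a (at least 32.5-fold, to below the array medians) and Ms4a4b (−4.33) fell with Ms4a6b, 3 of these 6 being members of the monocyte list. Ms4a7 (−0.55) turned to 0.20 with ribosomal centring. The 2 that rose were Ms4a3 (1.35) and Ms4a2 (1.74), known from granulocyte precursors and from basophils and mast cells.

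Of the PYHIN family of interferon-inducible genes, which includes DNA sensors, 5 of 8 tested genes were lower. Aim2 (−0.16), Ifi204 (−0.39) and Ifi202b (0.16) did not pass. Ifi209 fell by 5.14, Mndal by 4.21, Ifi207 by 3.19, Ifi203 at least 1.26-fold to below the array medians and Ifi213 from 7.17 to a mean below them, and with ribosomal centring 4 were lower and 2 higher. C-type lectin genes split, with 4 of 17 lower and 6 higher, and with poly-A centring 8 lower and 2 higher. Clec10a (−5.16), Clec2i (−4.61) and Clec4a3 (−3.70) fell, while Clec4n (1.58), Clec4d (0.65) and Clec4e (0.48) rose, the last pair being members of the mature neutrophil list.

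Immunoglobulin transcripts were lower in GFP_hi: Igha fell from 12.90 ± 0.04 to 8.94 ± 0.19, Jchain from 10.88 ± 0.05 to 6.70 ± 0.78, and Ighm by 0.46, the last turning to 0.29 with ribosomal centring. B cells in the GFP_lo sort stay open. The mean of 8 B cell genes was 0.081 higher in GFP_hi (SD 0.036) but −0.36 with poly-A centring. Only 2 lay over 1 log2 above the array medians in GFP_lo, Bank1 (7.00 and 7.32) and Cd79b (5.75 and 5.04). Plasma cells or their RNA, which a CD11b and Gr1 gate should remove, may contribute: of 14 other plasma cell genes 10 were tested, of which 8 were lower, among them Mzb1 (−1.13) and Prdx4 (−5.85), and 1 higher, Fkbp11 (0.37), but with ribosomal centring 4 were lower and 4 higher. This stays open also because Sdc1 (2.73), Tnfrsf17 (2.47) and Derl3 (2.12) lay at the floor in GFP_lo and Irf4 is also in the dendritic cell list, so monocyte or dendritic cells could carry part of it.

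Granulocyte genes were higher in GFP_hi where monocyte genes were lower, and a candidate explanation is dilution of granulocyte RNA by monocyte RNA in GFP_lo. As the whole cause it would move early and late granulocyte genes alike, provided that the diluting cells expressed neither, which was not tested. The means of 6 primary granule genes and 8 late genes were 1.26 and 0.92 higher, a gap of 0.343 (SD 0.141). The groups did not overlap, but GFP_lo replicate b (0.91) and GFP_hi replicate b (0.96) lay close. Over the full fixed lists, the mean rise was 1.08 for 12 primary granule genes. It was 0.59 for 29 tertiary granule and mature neutrophil genes. Without that proviso the gap cannot decide whether dilution was the whole cause. Compression of bright probe sets could hold back secondary granule genes, since brighter genes shifted less across 21 of them (Spearman's rho = −0.787, permutation p = 8e-05, adjusted p = 0.000160 over 2 lists) and across 29 mature neutrophil genes (−0.598, both p = 0.000820; genes are not independent replicates). At the same mean level, in a linear model over genes, 13 of them still differed from 20 mature neutrophil genes by −0.27 (permutation p = 0.00070), which argues against compression as the whole reason for these. Dilution in whole or in part and compression in part stay open. So do compression for the 8 secondary granule genes brighter than every mature neutrophil gene (median 0.05) and a different mix of maturation stages. For each pattern here the reporter level, which was not tested as a cause, also stays open.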
